A study of Homo sapiens with 6 samples.

How the data were processed

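Total RNA was sequenced from Cal27 cells, a human line from a squamous carcinoma of the tongue, in 3 groups of 2 biological replicates. Per the labels, the libraries were stranded and read in pairs, and all 6 carry batch 1. The deposited table holds counts, that is raw reads per gene, for 57820 versioned Ensembl gene identifiers in 6 libraries. Its values are whole numbers with no normalization. The processing notes name bcl2fastq, FastQC 0.11.7, STAR 2.6, HTSeq 0.6.1 and edgeR, and several genome builds, without saying what each was used for. The annotation and the strand setting of the counting are not stated. No sequence of the vectors was among the counted genes, so GFP itself has no value.

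Gene names and coordinates were taken from GENCODE release 44 (GRCh38) by the identifier without its version. Of the identifiers, 51996 had a name there and 5824 had none, and 1499 of the tested genes stayed unnamed. Genes were kept by edgeR's filterByExpr with the groups given (minimum count 10, minimum total 15), which left 16396 genes holding 99.9% of the counts. Levels of single libraries are given in CPM, counts scaled to a common library size, with the library sizes multiplied by TMM factors.

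All 6 libraries were fitted together with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, no covariate), since 2 libraries leave 1 degree of freedom per group, so that the groups share 1 estimate of the spread. The square root of the common dispersion was 0.289 and the prior degrees of freedom were 5.83. The contrasts were CRNN against GFP, CRNN against untreated, and GFP against untreated. P values are two-sided and were adjusted over all tested genes by Benjamini and Hochberg, and a gene rose or fell when its adjusted p was under 0.05. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of F. The replicate numbers were not used to pair libraries. Across 11729 genes, the differences between replicates 1 and 2 had r = 0.26 between CRNN and GFP, -0.071 between CRNN and untreated, and 0.19 between GFP and untreated.

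For 29 gene lists, limma 3.58.1 camera compared the members with all other genes at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Members were also counted as passing when their p was adjusted over the list alone. The contrasts, tests, gene lists, most alternatives and the rule for naming genes were fixed before the data were examined. Under that rule the text may name CRNN, the genes with the largest changes among those passing whose libraries do not overlap (12 each way for CRNN against GFP, 8 each way for the others, or the 5 smallest p-values where none passes), up to 4 members per list with the smallest adjusted p, and up to 10 genes changed against both controls.

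Alternatives were RLE, upper-quartile or no scaling factors beyond library totals, no filter, a filter of 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, robust edgeR, a fit of only the 2 groups compared, a replicate block, removal of the 10 most abundant genes, stricter thresholds, and each library left out in turn. Chosen after the data were seen were limma-voom with library weights, edgeR with its newer dispersion method, a correction of GC content and length, that correction with the replicate block, the upper-quartile and library-total scaling of the gene list tests, and a division of the untreated libraries between the comparisons that share them. The correction removed each library's trend with natural splines of 4 degrees of freedom, for which 97.2% of tested genes had values.

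The procedure was tested on simulated counts for CRNN against GFP, with 200 of 16396 genes changed in 5 runs. It recovered 10.4% of genes changed 2-fold, 81.6% at 4-fold, 98.4% at 8-fold and 100% at 16-fold, with a mean of 13.2 false calls. The changed genes were drawn from those with an average log2 CPM of at least 1. Each gene had the same spread in every library. The real replicates differed unequally between groups, so recovery in the data can be lower. There IFI44L and OAS1, at log2 fold changes of 4.13 and 2.84 for CRNN over GFP, had an adjusted p of 0.597 (edgeR). In the simulations camera called 1 of 145 lists without an effect, and called a list moved by a log2 fold change of 1 in 5 of 5 runs. Genes were simulated independently, so these runs do not show how often camera calls lists whose members vary together. In the data the estimated correlation of the interferon-stimulated list was 0.717 for CRNN against GFP. Library totals ranged from 11817105 to 28041227 counts, so 3 counts corresponded to between 0.107 and 0.254 CPM.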

Results

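Cornulin (CRNN) is a protein of the differentiating squamous epithelium that belongs to the S100 fused-type family. RNA was sequenced from Cal27 oral carcinoma cells that carried CRNN on a lentivirus, from cells with a GFP vector, and from untreated cells, with 2 biological replicates in each group. Per the labels, transduced cells were harvested 48 h after transduction with 8 µg/ml polybrene. For the untreated cells the labels give neither a harvest time nor polybrene, so comparisons with them cannot separate these from transduction. Library totals were 22990621 and 21735893 counts for CRNN replicates 1 and 2, 19572907 and 11817105 for GFP, and 28041227 and 24300844 for untreated cells. Between 24870 and 27282 genes had counts in a library, and mitochondrial transcripts took between 22.5% and 29.3% of the counts, mostly ribosomal RNA.

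CRNN transcripts were abundant in the CRNN cells and scarce in both controls. The gene (ENSG00000143536.7; GRCh38 chromosome 1, 152409243 to 152414263, minus strand) had 996 CPM ± 45.6 (SD, n = 2) in the CRNN cells, 2.81 ± 0.361 (SD, n = 2) in the GFP cells and 2.80 ± 1.01 (SD, n = 2) in untreated cells. These levels rest on 21256 and 23062 counts, on 59 and 32 counts, and on 92 and 52 counts. CRNN rose 352-fold over GFP (log2 fold change 8.46, SE 0.43, adjusted p = 2.24e-04) and 355-fold over untreated cells (8.47, SE 0.43, adjusted p = 2.11e-04). Over GFP it did not pass without GFP replicate 1 (8.61, adjusted p = 0.0754) or without GFP replicate 2 (8.37, adjusted p = 0.115). It did not differ between the 2 controls by more than its error (log2 fold change 0.011, SE 0.34, adjusted p = 0.994).

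The libraries did not stand equally close to each other. Untreated replicate 1 lay at 87.5 on the first principal component, which held 44.3% of the variance, and the other 5 libraries lay between -32.2 and -7.94. Of 11729 genes with a mean log2 CPM of at least 1, 110 were more than 4-fold higher in untreated replicate 1 than in every other library and 44 were more than 4-fold lower. In GFP replicate 1 these counts were 8 and 14, in GFP replicate 2 they were 1 and 1, and in the other 3 libraries they were 0. The median SD between replicates was 0.11 log2 CPM for CRNN, 0.30 for GFP and 0.26 for untreated cells. Across genes of a library, which are not independent replicates, the level against the other libraries followed GC content with rho = 0.653 in GFP replicate 1 and -0.402 in GFP replicate 2. With transcript length rho was 0.448 in GFP replicate 2 and -0.302 in CRNN replicate 2.

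The comparison of CRNN with the GFP vector asks which transcripts differ when the cells carry CRNN in place of a control insert. Of 41 tested genes that type I interferon induces, 2 rose in the CRNN cells over all genes. IFI6, an interferon-induced protein of the mitochondrion and endoplasmic reticulum (ENSG00000126709.10; chromosome 1, 27666064 to 27672212), had 445 and 514 CPM in the CRNN libraries against 15.6 and 19.95 in GFP, and rose by a log2 fold change of 4.76 (SE 0.49, n = 2 per group). IFI27, another interferon-induced gene (ENSG00000165949.8; chromosome 14, 94104836 to 94116695), had 329 and 404 CPM against 11.6 and 8.54, and rose by 5.18 (SE 0.54, n = 2 per group). Both had an adjusted p of 0.0307, and after the correction of GC content and length neither passed (IFI6 at 4.51, SE 0.52, adjusted p = 0.303; IFI27 at 5.01, SE 0.53, adjusted p = 0.238). In untreated cells IFI6 had 90.4 and 35.3 CPM and IFI27 had 99.9 and 34.7 CPM. With CRNN these were the 3 genes that rose among 16396, and none fell. At an unadjusted p under 0.05 there were 719 genes, 244 higher and 475 lower in CRNN, which is 4.39% of the tests. The shared spread of this fit takes in the untreated pair, whose replicates had 330 genes over 4-fold apart, against 67 in GFP and 6 in CRNN. With only the CRNN and GFP libraries fitted, edgeR called 13 genes, 8 of them on the interferon-stimulated list. DESeq2 on all libraries called 21, with 9 on that list, and limma-voom called 3, with 2 on it.

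The interferon-stimulated list had 41 tested members, and all 41 had a positive log2 fold change, with a median of 1.48 and quartiles of 1.13 and 2.09. Over all genes 2 of them rose, and adjusted over the list alone 30 rose, 0 fell and 11 did not pass (edgeR, with 30 at an unadjusted p under 0.05). Among the examples, OAS1, which makes the 2-5A that activates RNase L, rose by 2.84 (SE 0.51) adjusted over the list alone. IFI44L rose by 4.13 (SE 0.74), from 0.883 and 3.27 CPM in GFP to 34.7 and 35.3 CPM in CRNN. The list was higher by camera (adjusted p = 2.28e-70; adjusted p = 0.744 with an estimated correlation). Its mean level, as log2 CPM centred per gene, was 0.80 and 0.90 in the CRNN libraries, -1.61 and -0.53 in GFP, and 0.86 and -0.42 in untreated cells, as the map of list levels shows. Without GFP replicate 1 the median was 1.21 and 2 members rose over the list alone, and without CRNN replicate 2 the median was 1.44 and 18 members rose. Without GFP replicate 2 the median was 2.22, and 36 members rose.

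**Figure D1:**
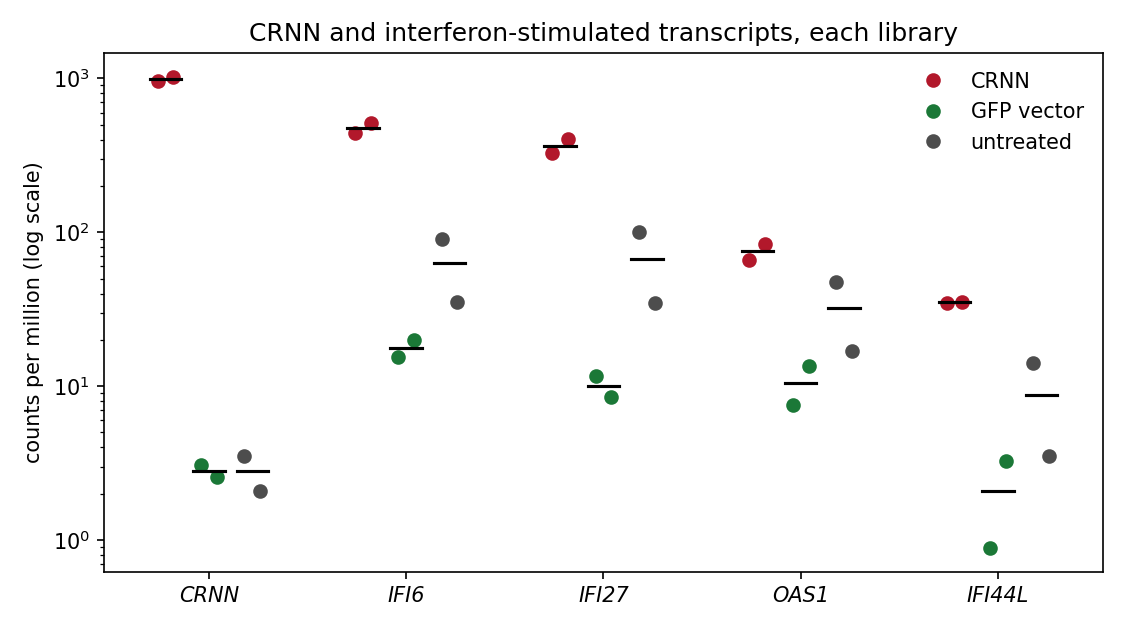
Level of CRNN and 4 interferon-stimulated genes in each of the 6 libraries, in CPM on a log axis, with points for libraries and bars for the mean of each group. CRNN has 964 and 1028 CPM in the CRNN libraries and at most 3.51 in the others, while IFI6 and IFI27 are lowest in the GFP libraries.

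**Figure D2:**
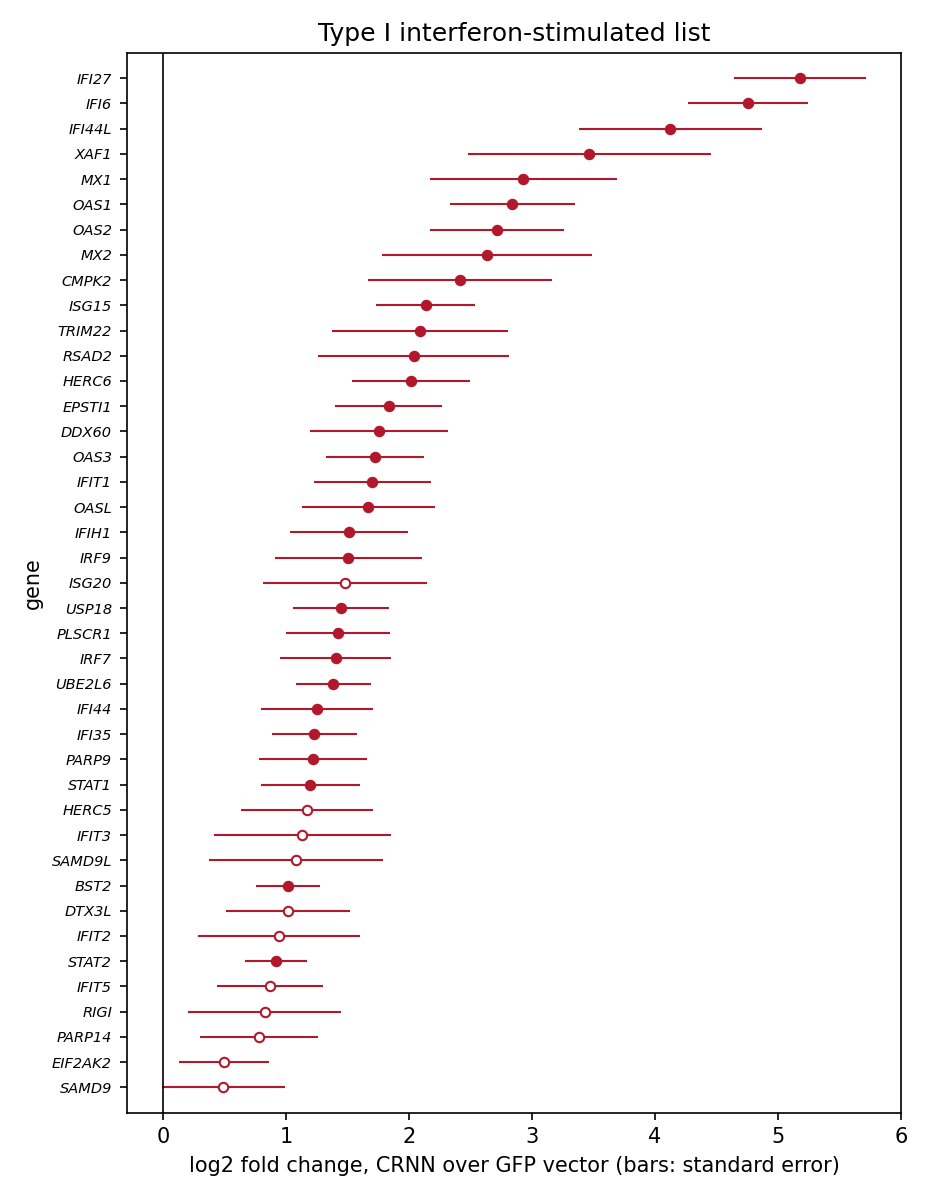
Log2 fold change of CRNN over GFP for the 41 tested interferon-stimulated genes, with bars for the standard error and 2 libraries per group. Filled points are the 30 genes with an adjusted p under 0.05 over the list alone, open points the other 11, and all 41 lie above 0.

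Other groups of genes also differed between CRNN and GFP. Antigen presentation genes were higher, with 18 of 19 members positive and a median of 0.84 (camera, adjusted p = 3.66e-09; adjusted p = 0.744 with an estimated correlation). No member passed over all genes or over the list alone, and 5 had an unadjusted p under 0.05 by edgeR. PSMB8 and PSMB9, subunits of the immunoproteasome, had log2 fold changes of 0.89 (SE 0.28) and 0.90 (SE 0.29). Without untreated replicate 1, whose level on this list was 0.62 against -0.35 in replicate 2, 9 members rose over the list alone, and without untreated replicate 2 also 9.

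Genes of the cornified envelope and squamous differentiation were lower in CRNN than in GFP, with 29 of 38 members negative and a median of -0.84 (camera, adjusted p = 1.76e-05; adjusted p = 0.744 with an estimated correlation). None passed over all genes or adjusted over the list alone, while 8 had an unadjusted p under 0.05 downward and 1 upward by edgeR. SPRR2G, a small proline-rich protein of the envelope, had 2 and 5 counts in CRNN against 49 and 13 in GFP, and SBSN had 28 and 23 counts against 77 and 29. GFP replicate 1 had the highest list level, 0.72 against 0.041 in GFP replicate 2. Without GFP replicate 1 the median was -0.017 and the list no longer passed (adjusted p = 0.467), and without CRNN replicate 1 it was -1.29. With replicate 1 of the untreated cells left out, the test put 6 members lower and 1 higher over the list alone, and without untreated replicate 2 it put 5 lower and 1 higher.

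The 13 mitochondrially encoded messenger RNAs, kept as a sign of RNA quality, were lower in CRNN, with a median of -1.05 (camera, adjusted p = 1.81e-15; adjusted p = 0.744 with an estimated correlation). Over all genes none passed, and adjusted over the list alone 7 fell and 6 did not pass, among them MT-ND2 at -1.41 (SE 0.38) and MT-ND1 at -1.42 (SE 0.40), both subunits of complex I. Their level was -0.98 in CRNN replicate 2 and -0.059 in CRNN replicate 1. Without CRNN replicate 2 the median was -0.63, without CRNN replicate 1 it was -1.59, and 0 members fell over the list alone without CRNN replicate 2, GFP replicate 1 or GFP replicate 2, against 12 after the correction of GC content and length. Nuclear genes of oxidative phosphorylation were higher, with 30 of 32 positive and a median of 0.29 (camera, adjusted p = 1.46e-04; adjusted p = 0.921 with an estimated correlation), which passed no more after the correction of GC content and length (median 0.082, adjusted p = 0.0643). Without CRNN replicate 2 their median was 0.18, and without GFP replicate 2 it was 0.19.

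Further lists that passed in CRNN against GFP depended on single libraries. Ribosomal protein genes had a median of 0.21, with 43 of 49 positive (camera, adjusted p = 0.00550; adjusted p = 0.952 with an estimated correlation), and did not pass without CRNN replicate 2 (0.083, adjusted p = 0.573), without GFP replicate 2 (0.12, adjusted p = 0.446) or after the GC and length correction (-0.016, adjusted p = 0.852). Their median was 0.38 without GFP replicate 1 (adjusted p = 8.52e-06) and 0.33 without CRNN replicate 1 (adjusted p = 7.45e-05). The EGFR ligand and MAPK feedback genes had a median of -0.67, with 17 of 18 negative (camera, adjusted p = 0.00550; adjusted p = 0.952 with an estimated correlation). Their median was 0.26 without GFP replicate 1 (adjusted p = 0.528) and -1.19 without GFP replicate 2, and SPRY4, a feedback inhibitor of MAPK signalling, went from -3.02 (SE 1.05) to -0.81 without GFP replicate 1. Protease and invasion genes had a median of 0.12 and a mean of 0.41, with 13 of 21 positive (camera, adjusted p = 0.0328; adjusted p = 0.921 with an estimated correlation). They did not pass without GFP replicate 1 (median 0.19, adjusted p = 0.165), and their median was 0.27 without GFP replicate 2 and 0.073 after the GC and length correction (adjusted p = 0.0291). No member of these 3 lists or of the nuclear oxidative phosphorylation list passed over all genes or over the list alone by edgeR, and 0, 1, 2 and 2 members had an unadjusted p under 0.05. Over the list alone 1 EGFR and MAPK gene fell without GFP replicate 2, untreated replicate 1 or untreated replicate 2, while 3 protease genes rose without GFP replicate 2 and 1 without untreated replicate 2.

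The other 21 lists did not pass in CRNN against GFP (smallest adjusted p = 0.0587, for apoptosis regulators), and in 6 of them the median, the mean and the test differed in sign. They included the markers of fibroblasts (6 tested, median -0.36), immune cells (3 tested, median -0.38) and endothelial cells (4 tested, median -0.063). S100 proteins had a median of 0.26 and a mean of -0.12, and S100A2 had a log2 fold change of 1.08 (SE 0.36). In the basal keratinocyte list PLEC, a linker of hemidesmosomes, had -1.33 (SE 0.43), or -0.77 after the GC and length correction. With a GFP library left out some of these lists passed: without replicate 1, S100 proteins (0.66, adjusted p = 3.09e-04), histones (0.52, adjusted p = 1.38e-04) and fibroblast markers (-0.76, adjusted p = 0.0415), and without replicate 2, S100 proteins downward (median 0.076, adjusted p = 0.0421), histones (-0.40, adjusted p = 0.0441), heat shock (0.27, adjusted p = 0.0421), immediate early (-0.48, adjusted p = 0.0441) and apoptosis genes (0.35, adjusted p = 0.00415). Apoptosis regulators passed without CRNN replicate 1 too (0.19, adjusted p = 0.0179), and after the GC and length correction they (0.10, adjusted p = 0.0291) and Notch and Wnt targets (0.25, adjusted p = 0.0291) did. No gene passed by edgeR without GFP replicate 1 (933 at an unadjusted p under 0.05) or without GFP replicate 2 (1606), where IFI6 was at 4.60 and 4.97 and IFI27 at 5.43 and 5.01. DESeq2 called 21 genes and limma-voom 3, and without untreated replicate 1 or untreated replicate 2 edgeR called 13 and 15.

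The comparison of CRNN with untreated cells adds the transduction to the insert, and any difference in polybrene or harvest time. CRNN was the single gene that rose, and none fell, with 735 genes at an unadjusted p under 0.05 (250 higher, 485 lower; edgeR), while DESeq2 called 7 genes and limma-voom 1. By camera, lists of inflammatory and growth-signal genes were lower in the CRNN cells than in the untreated pair, and mitotic genes were higher (adjusted p = 0.744 with an estimated correlation for each). None of their members passed over all genes or over the list alone, and without untreated replicate 1 the NF-kB list was higher in CRNN (median 0.39) and the mitotic median was 0.032. Leaving out untreated replicate 1, edgeR called 4 genes, and without untreated replicate 2 it called 957.

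Interferon-stimulated genes had a median of 0.45 in CRNN against untreated cells, with 29 of 41 positive (camera, adjusted p = 4.22e-09; adjusted p = 0.744 with an estimated correlation). Over all genes none passed, and adjusted over the list alone IFI6 (2.93, SE 0.44) and IFI27 (2.44, SE 0.47) rose and 39 members did not pass. The median was 1.10 without untreated replicate 1, where 17 members rose over the list alone, and -0.031 without untreated replicate 2 (adjusted p = 0.894). Over the list alone 1 member rose without GFP replicate 1 and 1 without GFP replicate 2. IFI44L had 1.99 (SE 0.65), or 3.31 without untreated replicate 1 and 1.32 without untreated replicate 2.

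NF-kB and inflammatory cytokine genes had a median of -1.92, with 23 of 23 negative (camera, adjusted p = 2.76e-08; adjusted p = 0.744 with an estimated correlation). TNFAIP3, which restrains NF-kB signalling, had 291 CPM in untreated replicate 1 and 5.32 in replicate 2, against 9.29 and 8.29 in the CRNN libraries. CXCL8, a neutrophil chemoattractant, had 53.8 and 0.520 CPM in the untreated libraries against 1.31 and 1.47. With replicate 1 of the untreated cells left out, the list was higher in CRNN, with a median of 0.39 (adjusted p = 2.49e-05), and CXCL8 had a log2 fold change of 1.41 in place of -4.28, and TNFAIP3 0.73 in place of -4.07. None of its members passed over all genes or over the list alone by edgeR, with 9 at an unadjusted p under 0.05, while without untreated replicate 2 the median was -2.82 and 20 fell over the list alone.

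EGFR ligand and MAPK feedback genes had a median of -1.81, with 17 of 18 negative and 12 at an unadjusted p under 0.05 (camera, adjusted p = 1.69e-09; adjusted p = 0.744 with an estimated correlation). Immediate early genes had a median of -0.58, with 15 of 18 negative and 5 at an unadjusted p under 0.05 (adjusted p = 3.09e-04; adjusted p = 0.744 with an estimated correlation). HBEGF, a ligand of EGFR, had -3.65 (SE 1.21) and JUN, a subunit of AP-1, had -3.49 (SE 1.22), and no member of these lists passed over all genes or over the list alone by edgeR. Without untreated replicate 1 the medians were -0.15 (adjusted p = 0.226) and 0.19 (adjusted p = 0.223), with HBEGF at 0.074 and JUN at 0.20. Without untreated replicate 2 the immediate early median was -1.05, and 13 and 11 members of the lists fell over the list alone.

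Mitotic (G2/M) genes had a median of 0.60, with 30 of 32 positive (camera, adjusted p = 6.11e-10; adjusted p = 0.744 with an estimated correlation), and replication-dependent histone genes 0.49, with 11 of 11 positive (adjusted p = 4.59e-04; adjusted p = 0.744 with an estimated correlation). Mitotic genes were at -1.25 in untreated replicate 1 and between 0.033 and 0.52 in the other libraries. PLK1, a mitotic kinase, had 35.2 and 106 CPM in the untreated libraries and 131 and 141 in CRNN. With replicate 1 of the untreated cells left out, the medians were 0.032 (adjusted p = 0.920) and 0.24 (adjusted p = 0.165), and without untreated replicate 2 the mitotic median was 1.53 and 28 mitotic and 2 histone members rose over the list alone. By edgeR none passed over all genes or over the list alone with both libraries, and 1 mitotic and 0 histone members had an unadjusted p under 0.05.

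Further lists were lower in CRNN than in untreated cells by camera. They were cell junction genes (median -0.24, adjusted p = 0.00413), the unfolded protein response (-0.19, adjusted p = 5.40e-04) and cholesterol biosynthesis (-0.32, adjusted p = 5.40e-04), each with an adjusted p = 0.744 with an estimated correlation. Ribosomal protein genes (-0.18, adjusted p = 0.00423; adjusted p = 0.987 with an estimated correlation) and mitochondrially encoded messenger RNAs (-0.41, adjusted p = 5.40e-04; adjusted p = 0.759 with an estimated correlation) were lower too. Without untreated replicate 1 the first 4 did not pass, with medians of -0.051, -0.10, 0.031 and -0.060 (adjusted p = 0.223, 0.0789, 0.920 and 0.294). Cell junction genes did not pass without CRNN replicate 1 (-0.22, adjusted p = 0.135) and ribosomal genes did not pass without it (-0.046, adjusted p = 0.853). The mitochondrially encoded list did not pass without CRNN replicate 2 (-0.071, adjusted p = 0.761) or untreated replicate 2 (-0.16, adjusted p = 0.679), and had -0.84 without CRNN replicate 1 and -0.62 without untreated replicate 1. Ribosomal genes had -0.31 without CRNN replicate 2 and -0.30 without untreated replicate 2, where cell junction and cholesterol genes had -0.36 and -0.63 and, over the list alone, 5 cell junction, 10 cholesterol and 9 unfolded protein genes fell and 1 cell junction gene rose. No member of these 5 lists passed over all genes or over the list alone by edgeR, where 3, 4, 3, 0 and 0 had an unadjusted p under 0.05. CDH1, the adhesion protein E-cadherin, had -1.38 (SE 0.39), or -0.60 without untreated replicate 1.

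Notch and Wnt target genes were higher, with 14 of 19 positive and a median of 0.16 (camera, adjusted p = 0.00496; adjusted p = 0.744 with an estimated correlation), and SP5, a target of Wnt signalling, had 1.67 (SE 0.43). No member passed over all genes or over the list alone by edgeR, and 3 had an unadjusted p under 0.05. The median was 0.63 without untreated replicate 2, where the list did not pass (adjusted p = 0.108) though 4 members rose and 2 fell over the list alone, 0.30 without untreated replicate 1, and 0.24 without CRNN replicate 2.

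The other 17 lists did not pass (smallest adjusted p = 0.189, for endothelial markers), and in 8 of them median, mean and test differed in sign. The medians were 0.15 for fibroblast, -0.14 for immune and -0.43 for endothelial markers, and 0.094 for squamous differentiation. The squamous median was -0.17 without CRNN replicate 1 and 0.17 without untreated replicate 2. In the mesenchymal list, adjusted over the list alone, VIM (vimentin) rose by 2.29 (SE 0.52), from 0.267 and 0.480 CPM to 1.59 and 2.10 CPM, and CCN1 (-3.83, SE 0.99) and CCN2 (-5.59, SE 1.44), matricellular proteins, fell. The endothelial cadherin CDH5, expressed in every library, fell by 1.96 on the log2 scale adjusted over its list alone. It had 49.9 CPM in untreated replicate 1 and between 7.21 and 12.6 in the other libraries, and CCN2 had 115 and between 1.16 and 6.08. With replicate 1 of the untreated cells left out, CCN1, CCN2 and CDH5 were at -1.03, -0.98 and -0.60, and the mesenchymal list was higher with 2 members that rose over the list alone (median 0.29, adjusted p = 3.90e-05). Without untreated replicate 2 that list was lower, with a median of -0.63 (adjusted p = 3.08e-08) and 2 members that rose and 10 that fell, the protease list was lower (-0.34, adjusted p = 3.85e-06), and without untreated replicate 1 antigen presentation (0.64, adjusted p = 4.18e-13) and protease genes (0.26, adjusted p = 0.00991) were higher. No mesenchymal gene passed over the list alone without CRNN replicate 2, GFP replicate 1 or GFP replicate 2, and CDH5 passed so with all libraries and without untreated replicate 2, but not when any of the other 5 was left out. After the GC and length correction no member of the mesenchymal or the endothelial list passed over the list alone.

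**Figure D3:**
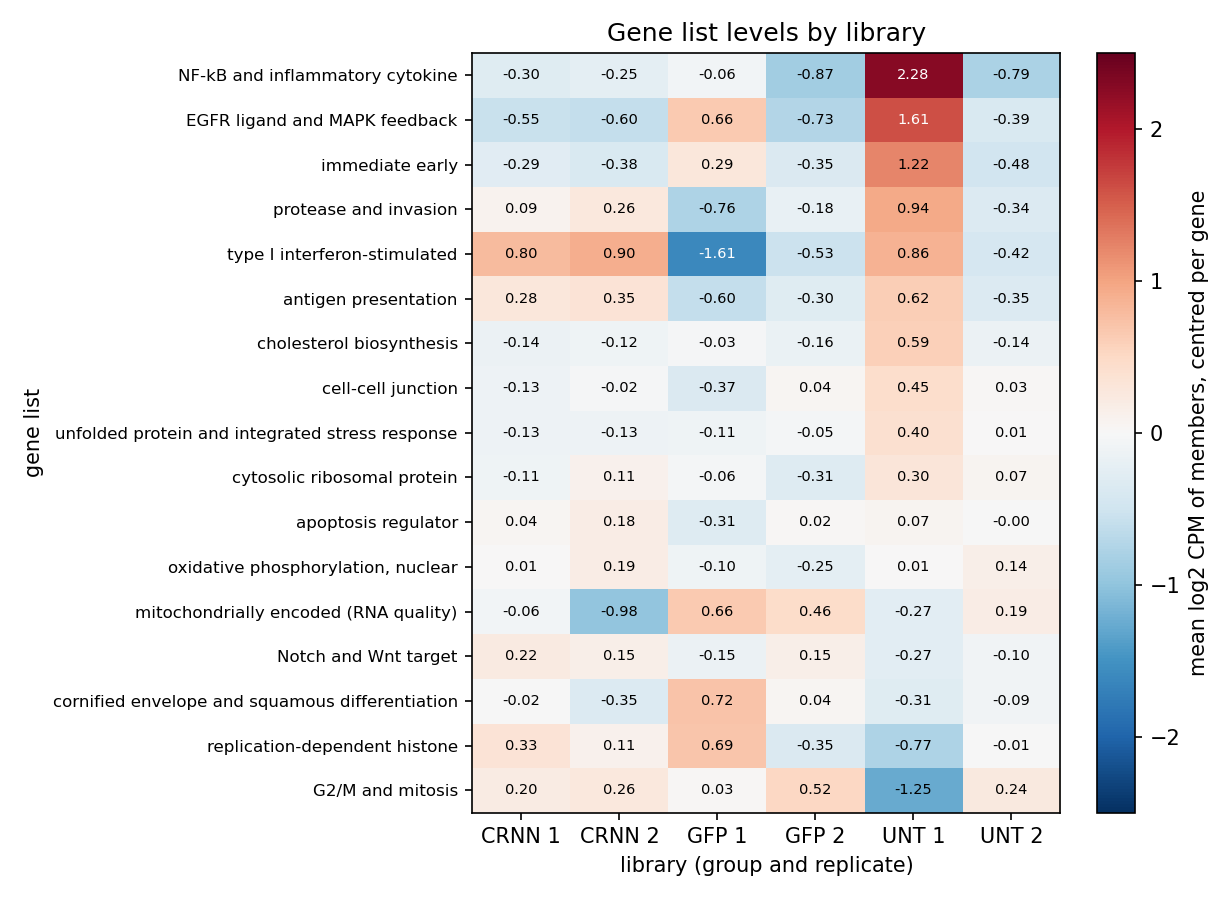
Mean level of 17 gene lists in each of the 6 libraries, as log2 CPM centred per gene and averaged over the members, with red above and blue below the mean of the 6 libraries. Untreated replicate 1 (UNT 1) has the highest value of the NF-kB list, 2.28, and the lowest of the G2/M list, -1.25, while the interferon-stimulated list is at 0.80 and 0.90 in the CRNN libraries.

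The comparison of the GFP vector with untreated cells asks what differs with transduction and the control insert, together with any difference in polybrene or harvest time. No gene passed by edgeR (smallest adjusted p = 0.711), with 1137 at an unadjusted p under 0.05 (661 higher, 476 lower), while limma-voom called 0 and DESeq2 29. Among the genes with the smallest p were EP400, which acts in a chromatin complex, with a log2 fold change of 1.71 (SE 0.30), BCORL1, a corepressor, with 2.02 (SE 0.39), and IFI27 and SBSN. By camera, lists of interferon-stimulated and inflammatory genes were lower in the GFP cells than in the untreated pair, and squamous and mitotic genes were higher (adjusted p = 0.591 with an estimated correlation for each). Single libraries carried several of these: the inflammatory list was higher in GFP without untreated replicate 1 (median 0.26, adjusted p = 0.0268), where the mitotic median was 0.027 and the interferon median -0.48, and the squamous median was -0.27 without GFP replicate 1. Without untreated replicate 2 edgeR called 966 genes, and without each of the other 5 libraries it called 0 (between 534 and 2060 at an unadjusted p under 0.05).

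All 41 interferon-stimulated genes were lower in GFP than in untreated cells, with a median of -1.25 (camera, adjusted p = 3.02e-27; adjusted p = 0.591 with an estimated correlation). Over all genes none passed, and adjusted over the list alone 19 fell and 22 did not pass. IFI27 fell by 2.74 (SE 0.48) and ISG15, a ubiquitin-like modifier, by 1.66 (SE 0.40) on the log2 scale over the list alone. Untreated replicate 1 had a list level of 0.86 and replicate 2 of -0.42, and GFP replicate 1 had -1.61 and replicate 2 -0.53. Without untreated replicate 1 the median was -0.48, with 1 member that fell over the list alone, IFI27 at -1.80 and ISG15 at -0.95. Without GFP replicate 1 the median was -0.87 with 0 members over the list alone, without GFP replicate 2 it was -2.03 with 30, and without untreated replicate 2 it was -1.79 with 31. After the GC and length correction the median was -1.10 and 1 member fell over the list alone. Antigen presentation genes had a median of -0.57, with 17 of 19 negative (camera, adjusted p = 2.19e-05; adjusted p = 0.591 with an estimated correlation), none passing over all genes or the list alone, and 4 at an unadjusted p under 0.05 by edgeR. With replicate 1 of the untreated cells left out, their median was -0.13 (adjusted p = 0.343), and without untreated replicate 2 it was -0.998 and 17 fell over the list alone.

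NF-kB and inflammatory genes had a median of -1.27, with 22 of 23 negative (camera, adjusted p = 3.43e-07; adjusted p = 0.591 with an estimated correlation). Adjusted over the list alone 5 fell, the chemokines CXCL1 (-3.97, SE 1.11), CXCL10 (-5.10), CXCL11 and CXCL8, and PTGS2 (-5.08, SE 1.51), which makes prostaglandin H2, while over all genes none did. CXCL11 had 178 counts in untreated replicate 1, 3 in replicate 2, and 0 and 1 in GFP. Without untreated replicate 1 the list was higher in GFP, with a median of 0.26 (adjusted p = 0.0268), CXCL1 was at -1.07, CXCL10 at -0.79, PTGS2 at 0.0075 and CXCL8 at 0.42 in place of -5.24. Over the list alone 0 members fell without that library, without GFP replicate 1 (median -2.30) and without GFP replicate 2, 8 fell without CRNN replicate 1 or CRNN replicate 2, and 19 without untreated replicate 2 (median -2.16). After the GC and length correction the median was -1.02 and 0 fell over the list alone.

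Squamous differentiation genes had a median of 0.74, with 28 of 38 positive (camera, adjusted p = 1.27e-04; adjusted p = 0.591 with an estimated correlation). Over all genes none passed, and adjusted over the list alone 4 rose, 1 fell and 33 did not pass. SBSN rose by 2.53 (SE 0.47), KRT1, a keratin of differentiating layers, by 1.79 (SE 0.49), and KRT13, a keratin of the oral mucosa, fell by 1.46 (SE 0.39) on the log2 scale over the list alone. SPRR2G rose from 3 and 0 counts to 49 and 13. The last, EVPL (0.94, SE 0.26), a precursor of the envelope, was named after its values were seen. Without GFP replicate 1 the list median was -0.27 (adjusted p = 0.336), and 10 members rose over the list alone without untreated replicate 2 and 2 without untreated replicate 1, while 3 rose and none fell without GFP replicate 2. After the GC and length correction 2 rose and none fell over the list alone (median 0.83). KRT1 was at 1.13 without GFP replicate 2, and KRT13 at -0.72 without untreated replicate 2. In the basal keratinocyte list, which did not pass (adjusted p = 0.997), the hemidesmosome integrin ITGB4 rose by 1.13 (SE 0.27) over the list alone. No member of that list passed so without CRNN replicate 1, CRNN replicate 2, GFP replicate 1 or GFP replicate 2, or after the correction, and 3 rose and 3 fell without untreated replicate 2.

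Mitotic genes had a median of 0.64, with 32 of 32 positive (camera, adjusted p = 1.23e-08; adjusted p = 0.591 with an estimated correlation), and MKI67, the Ki-67 antigen, had 337 and 775 CPM in GFP against 87.6 and 241 in untreated cells. Histone genes had a median of 0.53, with 11 of 11 positive (adjusted p = 0.00438; adjusted p = 0.591 with an estimated correlation). None of either list passed over all genes or the list alone by edgeR, with 3 and 0 at an unadjusted p under 0.05. With replicate 1 of the untreated cells left out, the medians were 0.027 (adjusted p = 0.884) and 0.26 (adjusted p = 0.343), and without untreated replicate 2 the mitotic median was 1.53 with 27 members that rose over the list alone. Without GFP replicate 2 the medians were 0.32 and 0.97, and without GFP replicate 1 the histone median was -0.11 (adjusted p = 0.596). The mitochondrially encoded messenger RNAs had a median of 0.70, with 13 of 13 positive (adjusted p = 9.87e-05; adjusted p = 0.591 with an estimated correlation), or 0.44 without untreated replicate 1.

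Ribosomal protein genes (median -0.40, adjusted p = 1.35e-07), nuclear oxidative phosphorylation genes (-0.27, adjusted p = 0.00167), protease genes (-0.30, adjusted p = 0.00157), cell junction genes (-0.28, adjusted p = 0.00198), cholesterol biosynthesis (-0.31, adjusted p = 0.00438), the unfolded protein response (-0.33, adjusted p = 0.00458), EGFR ligand and MAPK feedback genes (-1.02, adjusted p = 0.00637) and apoptosis regulators (-0.36, adjusted p = 0.0498) were lower in GFP by camera, each with an adjusted p = 0.591 with an estimated correlation. None of their members passed over all genes or over the list alone by edgeR, and from 0 to 5 of each had an unadjusted p under 0.05. Without untreated replicate 1 the EGFR and MAPK list was higher (median 0.44, adjusted p = 0.0239), and the protease (0.024, adjusted p = 0.839), cholesterol (-0.046, adjusted p = 0.908), unfolded protein (-0.13, adjusted p = 0.180) and apoptosis lists (-0.11, adjusted p = 0.189) did not pass. Without GFP replicate 1 the cell junction (-0.23, adjusted p = 0.253), protease (-0.22, adjusted p = 0.498), unfolded protein (-0.14, adjusted p = 0.0650) and apoptosis lists (-0.26, adjusted p = 0.498) did not pass. Without GFP replicate 2 the EGFR and MAPK (-0.45, adjusted p = 0.632), cholesterol (-0.20, adjusted p = 0.123) and oxidative phosphorylation lists (-0.18, adjusted p = 0.0752) did not pass, and neither did oxidative phosphorylation (-0.18, adjusted p = 0.207) and apoptosis (-0.29, adjusted p = 0.120) without untreated replicate 2. Over the list alone, leaving out untreated replicate 2 let 11 EGFR and MAPK, 9 protease, 9 cholesterol, 6 apoptosis, 5 unfolded protein and 3 cell junction genes fall. The EGFR and MAPK median was -1.90 without GFP replicate 1 and -1.65 without untreated replicate 2, the protease median -0.87 without GFP replicate 2 and -0.52 without untreated replicate 2, and the cell junction median -0.48 without untreated replicate 2. After the GC and length correction the medians were -0.21 for ribosomal (adjusted p = 1.67e-05), -0.11 for unfolded protein (adjusted p = 0.0118), -0.19 for protease (adjusted p = 8.77e-04) and -0.21 for apoptosis genes (adjusted p = 0.0369). The oxidative phosphorylation list did not pass after it (-0.067, adjusted p = 0.0682), and the apoptosis list not with RLE factors (adjusted p = 0.0507).

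The other 14 lists did not pass in GFP against untreated cells (smallest adjusted p = 0.0596, for immediate early genes), and in 2 of them median and test differed in sign. Immediate early genes passed without CRNN replicate 1 (-0.76, adjusted p = 0.0138), CRNN replicate 2 (-0.77, adjusted p = 0.0126), GFP replicate 1 (-0.74, adjusted p = 0.00888) and untreated replicate 2 (-1.28, adjusted p = 7.43e-08) and after the GC and length correction (-0.60, adjusted p = 0.0161), and were higher without untreated replicate 1 (0.39, adjusted p = 0.00102). Mesenchymal genes were higher without untreated replicate 1 (0.51, adjusted p = 2.28e-04) and lower without untreated replicate 2 (-0.64, adjusted p = 7.43e-08). Without GFP replicate 1 S100 proteins were lower (-0.69, adjusted p = 3.64e-04), and without GFP replicate 2 heat shock genes were (-0.34, adjusted p = 0.0199). Medians were 0.36 for fibroblast, 0.15 for immune and -0.47 for endothelial markers. S100 proteins had a median of -0.46, with S100A7, known as psoriasin, at 2.97 (SE 0.83), or 1.00 without GFP replicate 1. KRT17, a keratin of stressed and basal cells, had -2.97 (SE 1.00), or 0.068 without untreated replicate 1.

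CRNN alone was called against both controls, where 1.83e-04 shared genes were given by chance for genes that rose, and a mean of 0.1 in 20 simulations in which nothing changed and the CRNN libraries were shared. The count called against both was 0 without GFP replicate 1 or GFP replicate 2, without untreated replicate 1 it was 4 and without untreated replicate 2 it was 5, and it was 3 with DESeq2, 2 with library weights and 11 with no filter. The log2 fold changes of CRNN and of GFP against the shared untreated libraries were compared over tested genes with an average log2 CPM of at least 1. Across these genes, which are not independent replicates, r was 0.696, against 0.496 in the simulations, and the covariance was higher by 0.107 than the simulated one. Among all 16396 tested genes edgeR called 0 in both. A separate untreated library for each comparison was tried over 17539 genes without that cut on log2 CPM, so its values and those above rest on different genes. With the untreated libraries so divided, r was 0.041 for CRNN against replicate 1 and GFP against replicate 2, and 0.019 the other way round, with covariances of 0.030 and 0.012. There edgeR called 957 genes for CRNN and 0 for GFP, and 4 and 966 the other way round, so a count of shared calls decides nothing. Over tested genes with an average log2 CPM of at least 1, the fold changes of CRNN against GFP and against untreated cells had r = 0.335, where the simulations gave 0.496. The simulations gave each gene the same spread in every library. In the data 330 genes lay over 4-fold apart between the untreated replicates, against 67 in GFP and 6 in CRNN. A wider spread of the shared untreated libraries would raise their r and covariance without a shared effect. The gaps between data and simulations therefore decide nothing on such an effect.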

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

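The tests chosen after the data were seen were limma-voom with library weights, edgeR with its newer dispersions, the GC and length correction, that correction with the replicate block, upper-quartile and library-total scaling of the list tests, and the division of the untreated libraries between comparisons. The planned use of edgeR's legacy dispersions was the installed default and so no alternative. The counts of 3, 1 and 0 genes (CRNN against GFP, CRNN against untreated, GFP against untreated) were the same with RLE, upper-quartile or library-total scaling, a filter of 1 CPM, limma-voom, robust edgeR, without the 10 most abundant genes, with the newer dispersions and at 2-fold or more. Scaling moved the median of all genes by at most 0.0976 log2. With no filter they were 34, 152 and 195 (11 against both controls, 83 shared against untreated), with DESeq2 21, 7 and 29 (3 and 1), with library weights 6, 2 and 0 (2 against both controls), with only the 2 groups fitted 13, 1 and 0, with the replicate block 4, 1 and 0, with the GC and length correction 1, 1 and 0, also with the block, and at an adjusted p under 0.01 CRNN against GFP had 1. The cause was not tested, except that a fit of fewer libraries drops the spread of the rest. No filter adds genes, but this alone does not account for its calls. Of its 34 in CRNN against GFP, 15 were on the interferon-stimulated list, whose 41 members were tested in the main fit too. The adjusted p of CRNN went there from 2.24e-04 to 5.40e-17 (edgeR). For the GC and length correction the cause was examined in part, as given with the interferon-stimulated genes. Leaving out 1 library at a time, with the lone sample of its group assumed to vary like the others, gave 0 to 15, 1 to 957 and 0 to 966 genes, 0 to 5 against both controls, and 0 to 672 shared against untreated. CRNN's log2 fold change over GFP ranged from 8.37 to 8.61 and did not pass without GFP replicate 1 (8.61, adjusted p = 0.0754) or GFP replicate 2 (8.37, adjusted p = 0.115). Gene lists that passed camera numbered 8, 12 and 15, none with an estimated correlation (0, 0 and 0) or by fry (0, 0 and 0), and 7 to 12, 7 to 12 and 10 to 16 with a library left out. In GFP against untreated they numbered 14 with RLE or the filter of 1 CPM, and 16 with upper-quartile or library-total scaling. In CRNN against GFP they numbered 9 with the replicate block. No list that passed turned under these. Some values changed sign when a library was left out, and their ranges over those fits follow. Log2 fold changes of CRNN over untreated ran from their value without untreated replicate 2 to that without untreated replicate 1, for TNFAIP3 from -5.04 to 0.73, CXCL8 -5.26 to 1.41, CXCL10 -4.54 to 0.74, HBEGF -4.59 to 0.074, SERPINB2 -7.09 to 0.89, PLAUR -4.42 to 0.36, JUN -4.43 to 0.20 and KLF6 -3.50 to 0.36. The same held for GFP over untreated in PTGS2 (-6.07 to 0.0075), KRT17 (-3.89 to 0.068) and ERRFI1 (-3.81 to 0.11), and CXCL8 ran from -6.80 without GFP replicate 1 to 0.42 without untreated replicate 1. List tests turned without untreated replicate 1 in CRNN against untreated for NF-kB (medians -2.82 to 0.39), immediate early (-1.05 to 0.19) and cholesterol (-0.63 to 0.031), and in GFP against untreated for NF-kB (-2.30 to 0.26), EGFR and MAPK (-1.90 to 0.44, and also -0.45 without GFP replicate 2) and cholesterol (-0.45 to -0.046). They also turned without GFP replicate 1 for EGFR and MAPK in CRNN against GFP (-1.19 to 0.26) and for histones in GFP against untreated (-0.11 to 0.97). The cause was not tested. For the lists that passed with all libraries and the genes named, 374 other list medians and 1425 gene values stayed on their side of the threshold, 107 (among them each list with an estimated correlation and by fry) and 8 no longer passed, and 121 gene values passed anew. Lists that passed in an alternative alone are not in these counts. Depth limits genes near the filter: 3 counts are 0.254 CPM in the smallest library.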

Other observations

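Tests of single libraries, of transduction, of other cells and of YAP/TEAD targets, and the choice of the metallothioneins, were made after the results were seen. Metallothioneins, small proteins that bind zinc and copper, were picked because members were seen to be high in the CRNN libraries, so no test of them as a group is given. All 6 tested members (MT1E, MT1F, MT1G, MT1M, MT1X and MT2A, whose reads can be shared between paralogs) were higher in CRNN than in GFP, with a median log2 fold change of 1.78. All 6 were also higher than in untreated cells, with a median of 0.77, and 5 of 6 were lower in GFP than in untreated cells, with a median of -0.96. Over the fits that leave out 1 library the median ranged from 1.43 to 2.25 in CRNN against GFP and from 0.74 to 0.83 in CRNN against untreated, and after the GC and length correction it was 1.44 and 0.63. In GFP against untreated it was -0.61 without GFP replicate 1. MT2A had 479 and 493 CPM in CRNN, 150 and 169 in GFP, and 212 and 287 in untreated cells (log2 fold change over GFP 1.61, SE 0.28, adjusted p = 0.597), and passed in 2 of 21 alternatives. MT1X had 2.42 (SE 0.34, adjusted p = 0.25) and passed in 7 of 21.

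TAGLN, an actin-binding protein of smooth muscle, had 20.2 and 17.1 CPM in CRNN, 1.04 and 2.08 in GFP, and 125 and 0.721 in untreated cells. It passed in CRNN against GFP in 3 of 21 alternatives. Untreated replicate 1 had 387 CPM of EDN1 (endothelin 1), 1766 of FST (follistatin) and 57.6 of ANKRD1.

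The interferon-stimulated list was higher in CRNN than in GFP, with a median of 1.48. Bias by GC content or length as its whole cause is argued against by a median of 1.42 (quartiles 1.08 and 2.03) after that trend was removed. The calls of IFI6 and IFI27 ended there while their log2 fold changes went from 4.76 (SE 0.49) to 4.51 (SE 0.52) and from 5.18 (SE 0.54) to 5.01 (SE 0.53). Their p-values (edgeR) went from 4.89e-06 to 5.54e-05 and from 5.62e-06 to 2.91e-05, while the prior degrees of freedom went from 5.83 to 4.03, and with 5.83 kept they would be 1.37e-05 and 6.19e-06. Adjusted p-values were not computed with 5.83 kept, so whether the calls would have held is not shown. A single CRNN or GFP library is argued against by a smallest median of 1.21 over the fits that leave such a library out. Transduction as such is argued against by medians of GFP against untreated of -1.25, and -0.48 without untreated replicate 1. That holds if the GFP cells were transduced as labelled, which these counts cannot show. It also holds only if harvest time and polybrene, not labelled for untreated cells, did not lower the list in GFP. Mitochondrially encoded messenger RNAs, kept as a sign of RNA quality, went the other way, with medians of -1.05 in CRNN against GFP and 0.70 in GFP against untreated. Against untreated cells the median in CRNN was 0.45, or 1.10 without untreated replicate 1 and -0.031 without untreated replicate 2. The list's mean level in replicate 1 minus replicate 2 was 1.28 in untreated cells, -1.08 in GFP and -0.10 in CRNN. How far CRNN was raised and how far GFP was low is therefore not settled. What stays open, and may act together, is an effect of CRNN itself, such variation between replicates, and a difference between the virus preparations of CRNN and GFP, which the design confounds. A difference in RNA quality, which was not tested as a source, stays open too.

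The squamous differentiation list was lower in CRNN than in GFP, with a median of -0.84. A GC or length trend as the whole cause is argued against by a median of -0.86 after the correction. The median was -0.017 without GFP replicate 1, but the high level of the list in that library prompted this test. A cause in that library alone therefore cannot be told apart from an effect of CRNN with 2 GFP libraries, and what set it apart was not tested.

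Untreated replicate 1 stood apart from untreated replicate 2, with all 23 NF-kB and inflammatory genes higher in it, by a mean log2 difference of 3.07 (SD 1.70 over genes). The totals of replicates 1 and 2 were 28041227 and 24300844 counts, and the difference was 3.06 after both were thinned to the total of the smallest library. Thinning leaves levels scaled to library size the same on average, whatever raised them, so this test cannot decide on depth. A GC or length trend is argued against by a difference of 3.03 after the correction. Fibroblasts, immune or endothelial cells are argued against by the markers measured (6 of 7, PECAM1 not analysed here). COL1A1 was the highest of them at 3.07 CPM while THBS1 had 8900 CPM, and between 733 and 3310 in the other libraries (all without TMM factors). Yet the endothelial gene CDH5 had 49.9 CPM against 12.1 in replicate 2, and VWF had 2.85 against 0.988 (without TMM factors). COL1A1 was higher in replicate 1 too, and COL1A2, COL3A1, PTPRC and LYZ were lower. A change in cell density could be a source. Between these libraries 19 YAP/TEAD target genes differed by a median of 0.99 (quartiles 0.26 and 1.87, 15 higher), without ANKRD1, CCN1 and CCN2, which had been seen to be high (57.6 against 0.801, 373 against 29.0 and 115 against 2.40 CPM). All tested genes had a median of -0.0097, and the targets were not tested as a set. Their median lies just under the bound set for a change in density. That bound and the list were set after the libraries were seen, and 1 library is compared with 1, so this decides nothing. That source cannot be told apart from others that raise these genes. The design gives no biological difference between the untreated replicates, and other culture conditions stay open.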
